A study of Mus musculus with 8 samples.

How the data were processed

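Gene expression was measured by RNA sequencing in 8 whole uterine implantation sites of mice at embryonic day 7.5, with 4 libraries labelled BPH/5 and 4 labelled C57. Per the labels' protocols, sites were snap frozen, total RNA was purified with Trizol, and co-purified genomic DNA was removed. Per the same protocols, polyadenylated RNA went into libraries made with the NEBNext Ultra Directional kit, which keeps strand. The labels give every sample the strain tag C57Bl/6J and set the groups apart by genotype, BPH/5 or wildtype. Libraries are named here by group and replicate, as in their labels.

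Per the submitters' processing notes, cutadapt 1.8, TopHat2 2.0.13 and Cuffdiff 2.2.1 were used with the genome build mm10. The order of the steps, the settings, the strand option and the gene annotation are not given in the sources used here. Per the file headers, the deposited table is a Cuffdiff read group table with 1 value per gene symbol and replicate. It holds raw fragment counts, fragments scaled by 1 factor per library, and FPKM (fragments per kilobase of transcript and per 1e6 fragments). The deposited raw fragments are estimated counts, of which 1.08% were not whole within 1e-09, in 306 genes. They were rounded to whole numbers before testing. In the deposited scaled fragments, the ratio to the raw fragments was constant within a library to 9.6e-06, so they were used only to recover that factor. The deposited FPKM values entered only alternatives. The table held no row of another sample.

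The table listed 23361 genes. Cuffdiff marked the estimate as failed in at least 1 library for 13 genes, Actr3, Psap and Hnrnpa1 among them, and these were left out. They held at most 2.01% of a library's fragments. Of the remaining 23348 genes, 4105 had no fragment in any library, and no mitochondrially encoded gene was listed. Library totals ran from 21966594 to 27943295 fragments, so that 3 fragments, the limit that a count of 0 allows, stood for 0.107 to 0.14 counts per 1e6 (CPM). This limit covers counting error only, since PCR copies are not independent molecules. Within each group, pairs of libraries were compared by the chi-square of their counts per degree of freedom. It was 3.87 for C57 3 and 4 and 11.8 to 32.4 for the other pairs. No pair agreed within sampling noise, so each library was counted once, but separate libraries of the same RNA would also exceed that noise, and for C57 3 and 4, the closest pair, this was not excluded.

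The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, glmQLFit with robust estimation and glmQLFTest, R 4.3.3) on all 8 libraries, with filterByExpr, TMM normalization and no covariate. It kept 14884 genes. A gene is called where its p, adjusted over all tested genes by the Benjamini-Hochberg method, lies under 0.05. Fold changes are BPH/5 against C57. CPM values use the TMM-scaled totals and are given as mean ± SD of 4 libraries. Per-library log2 CPM used a prior count of 2. A fold against a group with no fragment is a lower bound set by 3 fragments per library, and with 1 to 3 fragments a ratio of counts with its 95% interval is given.

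Before the data were examined, 31 gene lists were fixed: angiogenic factors and receptors, complement components, complement regulators, decidual stromal genes, trophoblast genes, prostaglandin genes, cytokines and chemokines, interferon-stimulated genes, MHC genes, hypoxia and glycolysis, renin-angiotensin and vasoactive genes, leptin and lipid handling, progesterone and steroid metabolism, matrix metalloproteinases and inhibitors, collagens and matrix, cell cycle genes, oxidative stress genes, immediate early and heat shock genes, and markers of epiblast, visceral endoderm, parietal endoderm, erythroid cells, uterine natural killer cells, macrophages and dendritic cells, neutrophils, T and B lymphocytes, endothelium, smooth muscle, uterine epithelium and glands, mitochondrially encoded genes and Y-linked genes. The 29 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes, were run beside it. Neither the mitochondrially encoded list nor the Y-linked list had a tested member. A list's score in a library is the median over its members of log2 CPM minus the gene's mean over the 8 libraries.

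Genes were named by a rule fixed at the same time. It takes the 12 highest and 12 lowest by fold among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving unnamed the symbols of the form Gm plus digits or ending in Rik. It also takes up to 4 members of lowest p per list, and 16 genes whatever their result: Vegfa, Pgf, Flt1, Kdr, Eng, Vegfc, C3, C1qa, Cfb, Cfd, Cfh, Cd55, Cr1l, Ptgs2, Prl8a2 and Prl3d1. The text names some of the genes that the rule takes. Symbols are as the table gives them. Gene spans come from GENCODE M21, which annotates the same build (mm10, GRCm38). Of the symbols, 98.4% matched, some through older names in RefSeq. Some symbols, such as Tgoln2, Hbb-b1 and H2-L, had no single position there and are printed without one.

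The edgeR and camera steps were tested on simulated data for BPH/5 against C57 with 14757 genes. Recovery was 70.1% of 67 genes changed 1.5-fold, 91.0% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 8.8% of 205 calls were false. A planted list was called and 0 of 20 unchanged lists were. The simulated genes were drawn independently, so this does not test camera on lists whose genes move together. A planted trend with transcript length went from a correlation of -0.84 to -0.01 with its correction.

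Alternatives chosen before the data were examined were DESeq2 size factors, upper-quartile scaling, library totals alone, no filter on low counts, at least 50 fragments in at least 4 libraries, DESeq2 1.42.0, limma voom with sample weights, edgeR without robust estimation, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, log2(FPKM + 1) without a filter, the replicate number as a block, and leaving out each library. Others were added after seeing the data: each library's trend with transcript length removed (lowess, span 0.3), the trends with length and GC content removed, C57 libraries 3 and 4 left out together, and every library thinned to the smallest total. Transcript length is that of the longest GENCODE transcript and was known for 99.2% of tested genes. Sequence shared between genes was measured as the share of 30-base words of a gene's longest transcript that the longest transcript of another gene also holds. The annotation and shared-sequence steps and the plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.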

Results

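RNA was sequenced from whole uterine implantation sites at embryonic day 7.5 of BPH/5 mice, an inbred strain whose pregnancies show features resembling preeclampsia, and of C57 mice. A site at this stage holds the early conceptus, the decidua that surrounds it, and the uterine wall with its glands, muscle, vessels and immune cells. Each group had 4 libraries. Library totals were 21966594, 27443524, 25633777 and 26078884 fragments for BPH/5 1 to 4 and 26731964, 24938989, 27943295 and 26944177 for C57 1 to 4. The labels do not say whether the 4 sites of a group came from separate dams, so the p-values measure only the spread between these samples, which may be technical. The comparison asks which genes, those of blood vessel growth and of complement among them, differ between the strains early in pregnancy.

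Among genes with a mean of at least 5 CPM in the higher group, no overlap between the groups and no Gm or Rik symbol, the 12 with the lowest folds in BPH/5 included Padi2, a peptidylarginine deiminase, at 56.6 ± 5.46 CPM (SD, n = 4) against 738 ± 90.6 in C57 (13-fold lower), and Tnfrsf23, a decoy receptor of the TNF receptor family, at 0.588 ± 0.112 against 46.3 ± 5.70 CPM (78.5-fold lower), though 32.9% of the 30-base words of its transcript also lie in another gene. Clca1 was 111-fold lower, Mndal, an interferon-inducible nuclear protein gene, 47.7-fold lower and Trim30d 41.1-fold lower. Igsf9, Slfn8, Grm4 and H2-T9 lay 14.1 to 15.4-fold lower. The 12 with the highest folds by the same rule included Tpsab1, a mast cell tryptase, at 78.2 ± 12.1 CPM against 1.46 ± 0.687 (53.7-fold higher). Gdpd3 (58.3-fold), the cartilage collagen gene Col9a1 (61.1-fold), Ifi202b (75.7-fold), AA465934 (35.9-fold), AI506816 (34.4-fold), Wfdc18 (33.2-fold), the immunoglobulin joining chain gene Igj, now Jchain, (33-fold), Bfsp1 (22.5-fold) and Gpr110, now Adgrf1, (17-fold) were higher as well. The adjusted p of these genes lay between 4.55e-10 for Tnfrsf23 and 0.000101 for Igj in edgeR's quasi-likelihood test. C57 1 had the highest C57 values of Col9a1 and Ifi202b and so lowered their folds. Without it their log2 fold changes rose from 5.93 to 7.01 and from 6.24 to 6.92. That of Wfdc18 fell from 5.05 to 4.21 without C57 3 and 4. Tnfrsf23 lies on chromosome 7 (143665809 to 143685872, minus strand), Padi2 on chromosome 4 (140906344 to 140952586, plus strand), Tpsab1 on chromosome 17 (25343245 to 25345562, minus strand) and Ifi202b on chromosome 1 (173962568 to 173982744, minus strand).

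Some genes had no or almost no fragments in BPH/5. Tgoln2 and Hbb-b1 had none in the BPH/5 libraries and 1092 and 522 in C57, so that they were at least 88-fold and 41.8-fold lower by the limit of 3 fragments per library. Trim12a had 3 fragments in BPH/5 and 1031 in C57, a ratio of 334 with a counting interval of 114 to 1620. Several of these genes have near-identical relatives between which the counting could split reads, and for Tgoln2, C1rb and Hbb-b1 the sum with a relative lay closer together between the groups. Tgoln1 and Tgoln2 together were at 282 ± 7.5 CPM in BPH/5 and 275 ± 13.1 in C57. C1rb alone was 64.8-fold higher in BPH/5 (log2 fold change 6.02, and 6.86 without C57 1), while C1ra and C1rb together were at 34.3 ± 2.60 against 31.5 ± 3.17 CPM. C1rb shared 72% of its 30-base words with another gene, Mndal 38.9%, Tnfrsf23 32.9%, AI506816 22.5% and Trim30d 12.7%, so that their single values, and those of Tgoln2 and Hbb-b1, are uncertain. Trim12a shared 8.55% and Ifi202b 1.5%, and H2-T9 had no matched transcript.

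Of 14884 genes tested, edgeR called 3680 higher and 3646 lower in BPH/5, together 49.2%. Most changes were small: the median called gene differed 1.39-fold, 689 genes were at least 2-fold higher and 618 at least 2-fold lower, and 200 and 167 were at least 4-fold higher and lower. In 82.4% of called genes, and 43.5% of tested ones, the 4 values of one group did not overlap those of the other, where chance gives 2.86%. The first principal component held 73.7% of the variance and parted the groups. Without C57 libraries 3 and 4 together, 2128 genes were called higher and 2090 lower. The counts of at least 2-fold changes moved with the processing: 420 genes were at least 2-fold higher under a stricter filter, and 275 were higher and 257 lower in limma on log2(FPKM + 1), which differed in test, normalization, filter and pseudocount.

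Libraries also differed in other ways, some that moved with the groups and some within a group. Across genes, which are not independent replicates, the log2 fold change fell with transcript length (Spearman's rho of -0.35). When the genes were put into 10 bins of about equal size by length, the shortest, up to 1384 nucleotides, had a median of 0.29 and the longest, from 6729 nucleotides, a median of -0.30 on the log2 scale. With each library's length trend removed, 3346 genes were called higher and 3397 lower, and 5585 of the 7326 calls (76.2%) kept their call and sign. C57 libraries 3 and 4 held 89 and 85 fragments of Y-linked genes, against 2 and 0 in C57 libraries 1 and 2 and 18, 6, 7 and 12 in BPH/5 libraries 1 to 4.

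**Figure D1:**
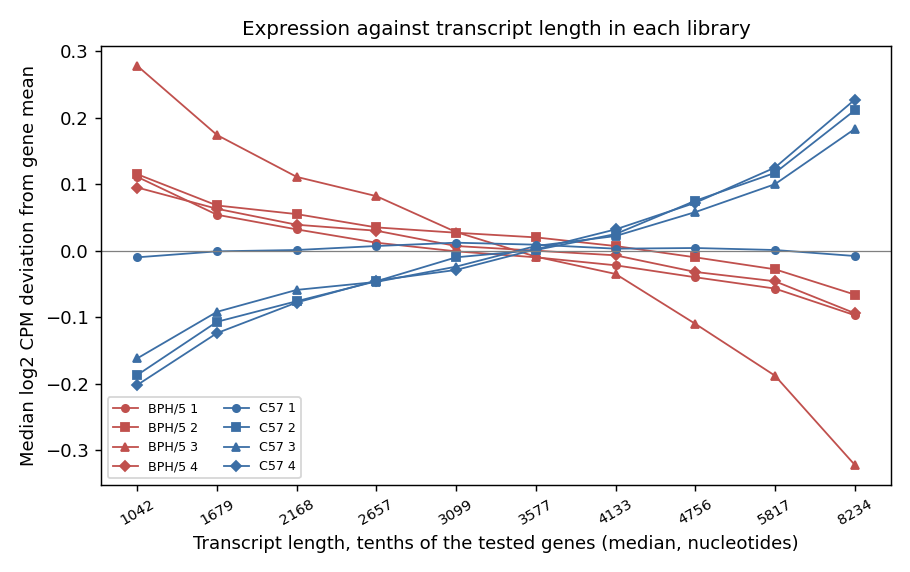
Median deviation of log2 CPM from each gene's mean over the 8 libraries (vertical axis, log2 scale), for 10 bins of tested genes by transcript length (horizontal axis, median length in nucleotides), with 1 line per library. BPH/5 libraries fall from short to long transcripts, BPH/5 3 the most (0.278 to -0.322), C57 2, 3 and 4 rise, and C57 1 stays within 0.012 of 0.

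Genes of blood vessel growth moved in both directions. Pgf, the placental growth factor gene (chromosome 12, 85166635 to 85177790, minus strand), was at 10.9 ± 1.20 CPM in BPH/5 against 5.25 ± 0.254 in C57, a log2 fold change of 1.05 with a standard error of 0.11 (edgeR adjusted p = 1.42e-05). Angpt1, an agonist of the receptor Tie2, rose 2.09-fold, and Dll4, a Notch ligand of sprouting vessels, rose 1.38-fold. Angpt2, which can oppose Angpt1 at the same receptor, fell from 711 ± 38.7 to 427 ± 64.4 CPM, 1.67-fold. The VEGF receptor gene Kdr (chromosome 5, 75932827 to 75978458, minus strand) was 1.41-fold lower, at 75.9 ± 9.49 against 107 ± 12.7 CPM (edgeR adjusted p = 0.00287). The coreceptor gene Eng (chromosome 2, 32646595 to 32682669, plus strand) was 1.38-fold lower, at 114 ± 10.6 against 157 ± 21.3 CPM (edgeR adjusted p = 0.00273), a call lost without C57 libraries 3 and 4 (edgeR adjusted p = 0.058, range over all alternatives 9.5e-05 to 0.058).

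The calls of Vegfa and Flt1 were near the threshold. Vegfa (chromosome 17, 46016993 to 46032369, minus strand) was at 285 ± 39.6 CPM in BPH/5 and 237 ± 19.3 in C57, 1.20-fold higher (edgeR adjusted p = 0.0386). Leaving out BPH/5 1 or 4 or C57 1, 3 or 4 ended that call (edgeR adjusted p = 0.11, 0.08, 0.079, 0.062 and 0.11), as did DESeq2 size factors (0.053), and the range over all alternatives was 0.011 to 0.22. Flt1, which encodes a VEGF receptor and its soluble form (chromosome 5, 147561604 to 147726011, minus strand), was at 31.1 ± 3.36 against 41.4 ± 8.01 CPM, 1.33-fold lower (edgeR adjusted p = 0.0293). That call ended without BPH/5 2 or 3 or C57 2, 3 or 4 (edgeR adjusted p = 0.053, 0.078, 0.08, 0.077 and 0.07) and with the length trend removed, when the log2 fold change went from -0.41 to -0.17 (edgeR adjusted p = 0.17, range over all alternatives 0.00042 to 0.26). Vegfc, at 4.19 ± 0.578 and 4.89 ± 0.713 CPM, did not pass (edgeR adjusted p = 0.234). Of the 31 tested angiogenic factors and receptors, 9 were higher, 10 lower and 12 not called (11 higher and 10 lower adjusted over the list alone). With the length trend removed, 9 were higher and 8 lower. Their median log2 fold change was -0.18, and the list did not stand apart from other genes (camera adjusted p = 0.87).

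**Figure D2:**
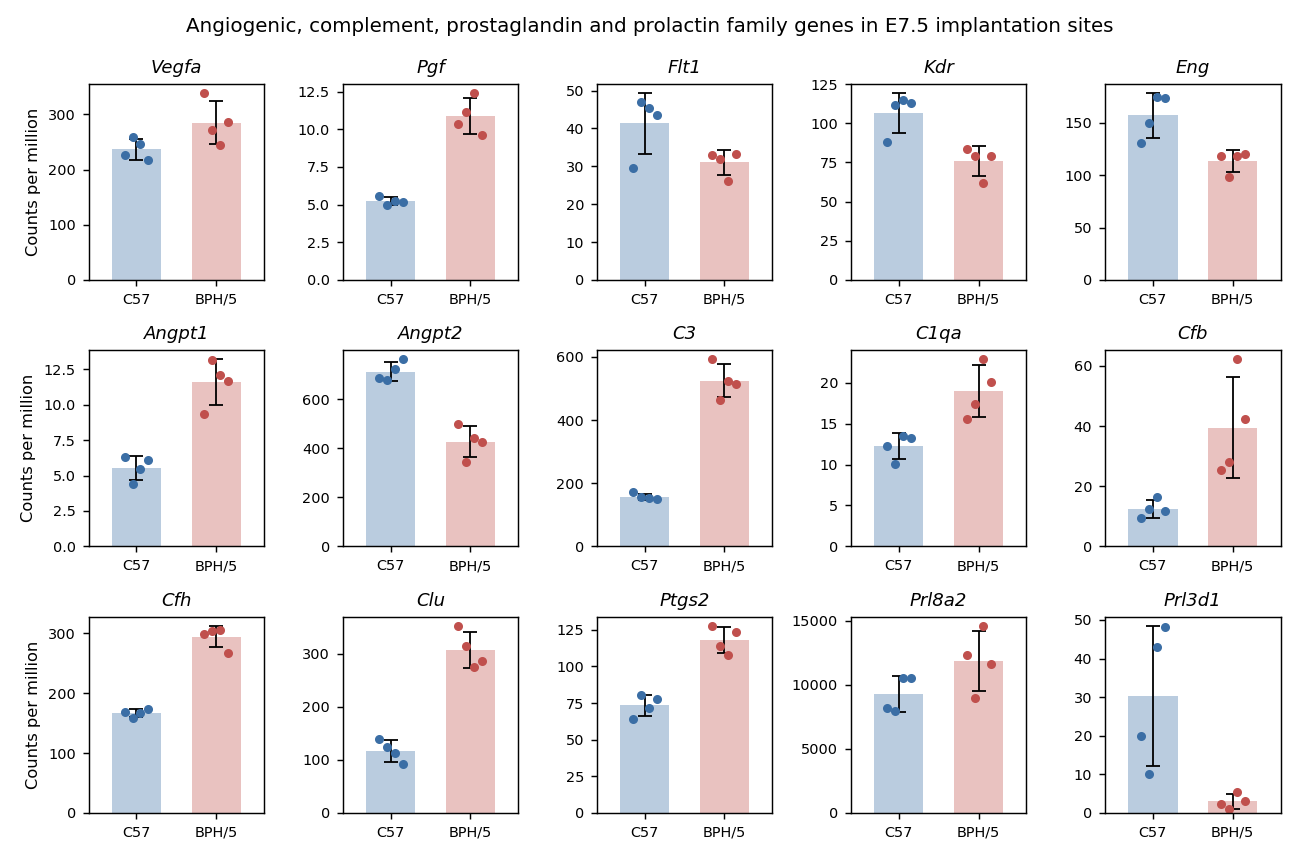
Normalized CPM (vertical axes, linear from 0) of 15 genes in C57 and BPH/5 implantation sites, with a point per library, bars at the group mean and error bars of 1 SD (n = 4). Pgf, Angpt1, C3, Cfb, Cfh, Clu and Ptgs2 are higher in BPH/5 and Angpt2, Kdr and Prl3d1 lower, while Vegfa and Flt1 lie closer together.

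Single genes of complement components changed in both directions. C3, the central component (chromosome 17, 57203970 to 57228136, minus strand), was at 524 ± 52.5 CPM in BPH/5 against 157 ± 9.58 in C57, 3.33-fold higher (edgeR adjusted p = 3.35e-08). Cfb, which joins C3b in the alternative pathway convertase (chromosome 17, 34856374 to 34862518, minus strand), was at 39.5 ± 16.9 against 12.5 ± 2.91 CPM, 3.17-fold higher (edgeR adjusted p = 0.00213). C1qa, a chain of the classical pathway's recognition molecule, rose 1.54-fold, and Masp2, a lectin pathway protease of low level here, was at 1.25 ± 0.229 against 0.0390 ± 0.0313 CPM. C1s (now C1s1), a classical pathway protease, fell 3.80-fold to 32.9 ± 2.76 CPM. Cfd, the factor D gene, had 9 fragments over all libraries and was not tested. Of 24 tested components and receptors, 9 were higher, 5 lower and 10 not called (10 and 6 adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 0.54).

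The complement regulators had 6 of 13 tested higher, 0 lower and 7 not called, the same counts adjusted over the list alone. Their median log2 fold change was 0.49, and the list was called (camera adjusted p = 0.027, but adjusted p = 0.83 with an estimated correlation). Cfi, the protease that inactivates C3b, rose 18.7-fold to 6.41 ± 0.901 CPM. Clu rose 2.63-fold to 307 ± 34.1 CPM, Cfh, the main soluble regulator of the alternative pathway, rose 1.77-fold to 295 ± 17.9 CPM, and the membrane regulator Cd55 rose 1.42-fold. Cr1l, which encodes the rodent regulator Crry, was at 53.6 ± 4.11 and 56.9 ± 1.92 CPM (edgeR adjusted p = 0.297). With no list was the estimated correlation's adjusted p under 0.05, and 7 or more lists were called in 18 of the 35 ways to split the 8 libraries into groups of 4, so the count of called lists alone does not set the groups apart. Fry, which does not compare a list with other genes, called 15 lists.

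Markers of the uterine epithelium and glands were higher in BPH/5. Of 28 tested, 22 were higher, 0 lower and 6 not called, the same counts adjusted over the list alone, and the median log2 fold change was 0.87 (camera adjusted p = 8.7e-08, and adjusted p = 0.092 with an estimated correlation). Epcam, an epithelial adhesion gene, rose from 19.7 ± 3.08 to 45.0 ± 2.77 CPM, 2.28-fold, and the simple epithelial keratin gene Krt18 rose 1.87-fold. Sox9 rose 4.41-fold. Ltf, encoding lactoferrin, rose 15.5-fold to 41.6 ± 17.3 CPM, Lcn2 rose 5.80-fold, and Spink3 (now Spink1) rose 4.31-fold to 143 ± 15.3 CPM. After correction for the length trend, 22 were higher and 2 lower. The list score was 0.43 to 0.52 in the BPH/5 libraries and -0.59 to -0.41 in C57. Whether BPH/5 sites held a larger share of epithelium, which could raise genes outside this list too, was not tested.

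Smooth muscle genes rose too, with 14 of 22 higher, 1 lower and 7 not called, the same adjusted over the list alone. Their median was 0.52 (camera adjusted p = 0.0047, and adjusted p = 0.83 with an estimated correlation). Hspb7, a small heat shock protein gene of muscle, rose 6.24-fold, Myl9 rose 2.16-fold and Tpm1 rose 1.87-fold. Matrix metalloproteinases and inhibitors had 11 of 21 higher, 3 lower and 7 not called, the same adjusted over the list alone, and a median of 0.35 (camera adjusted p = 0.027, and adjusted p = 0.83 with an estimated correlation). That call ended without C57 1 (camera adjusted p = 0.079, range over all alternatives 0.0002 to 0.83). Members of the list did unlike things: Mmp2 rose 1.96-fold, the plasminogen activator gene Plat 2.46-fold and the cathepsin inhibitor gene Cst3 2.37-fold, while Serpine1, an inhibitor of plasminogen activators, fell from 285 ± 50.7 to 52.0 ± 8.60 CPM, 5.47-fold. Collagens and matrix genes (13 higher, 5 lower and 8 not called of 26, the same adjusted over the list alone) had a median of 0.25 and were not called (camera adjusted p = 0.15). They were with the length trend removed (camera adjusted p = 0.0055, range over all alternatives 0.0048 to 0.83). Col3a1 rose 1.5-fold and Lama4 1.44-fold, and Eln, the elastin gene, fell 2.85-fold.

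**Figure D3:**
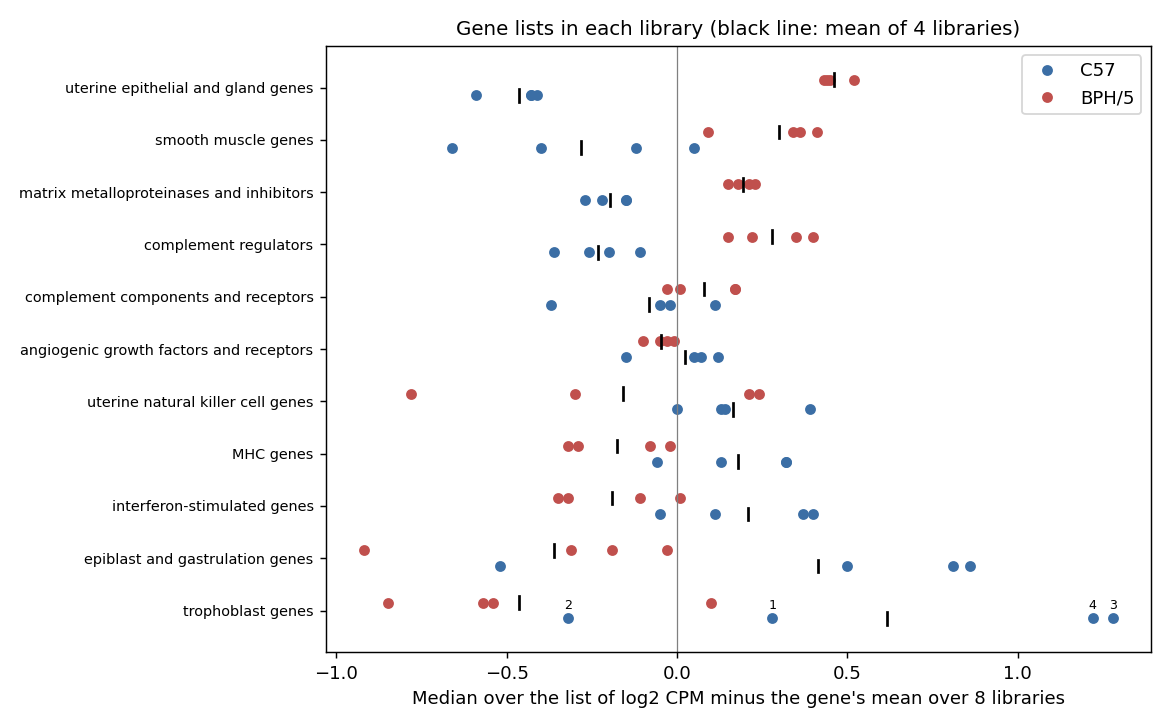
List score of each library (horizontal axis, log2 scale: the median over a list's genes of log2 CPM minus the gene's mean over 8 libraries) for 11 gene lists, with a point per library and a black line at each group's mean (n = 4). Uterine epithelial genes part the groups widely, while the trophoblast score of C57 2 (-0.32) lies among BPH/5 values and those of C57 3 and 4 (1.28 and 1.22) lie far above (numbers mark C57 libraries).

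Trophoblast genes were lower, unevenly between libraries. Prl3d1, a placental lactogen gene of trophoblast giant cells (chromosome 13, 27094190 to 27100258, plus strand), was at 2.95 ± 1.84 CPM in BPH/5 against 30.3 ± 18.2 in C57, a log2 fold change of -3.37 with a standard error of 0.60 (edgeR adjusted p = 0.00192). Prl3d1, Prl3d2 and Prl3d3 are near-identical, so single values are uncertain, and their sum was 3.41 ± 1.78 against 35.2 ± 20.4 CPM, 10.3-fold lower. Prl6a1 and Prl7a2, other prolactin family genes of the list, rose 3.45-fold and 1.92-fold. Of 22 tested, 3 were higher, 12 lower and 7 not called (3 and 13 adjusted over the list alone), with a median of -1.24 (camera adjusted p = 0.039, and adjusted p = 0.83 with an estimated correlation). The call ended without C57 3 (camera adjusted p = 0.069) or C57 4 (0.079), whose scores were highest and which held most of the Y-linked fragments, and without both (0.15). The stricter filter, which tests fewer genes, also ended it (0.24), and the range over all alternatives was 8.6e-05 to 0.83. Without C57 3 and 4, the median of the list was -0.41, and the log2 fold change of Prl3d1 was -2.36 (edgeR adjusted p = 0.015).

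Markers of the other conceptus tissues were not called as lists. Epiblast and gastrulation genes had 1 of 11 higher, 6 lower and 4 not called (1 and 7 adjusted over the list alone) and a median of -1.12 (camera adjusted p = 0.11, 0.033 without C57 2, and 0.033 to 0.83 over all alternatives). L1td1 fell 2.17-fold. Visceral and yolk sac endoderm genes had 5 of 18 higher, 7 lower and 6 not called (6 and 8 adjusted over the list alone) and a median of -0.34 (camera adjusted p = 0.87). Rbp4, the retinol carrier gene, fell 5.43-fold, and Apob fell 5.70-fold, while Spink3 of the same list rose. Parietal endoderm genes had 7 of 15 higher, 3 lower and 5 not called, the same adjusted over the list alone, with a median of 0.03 (camera adjusted p = 0.22). Stra6, a receptor for retinol-binding protein, rose 3.59-fold and Pdgfra fell 1.59-fold. Of 6 tested erythroid genes, only Hbb-b1 was called, lower (median -0.23, camera adjusted p = 0.24), also adjusted over the list alone. Hbb-b1 and Hbb-b2 together were 2.59-fold lower, and Alas2 was at 3.35 ± 0.838 and 4.04 ± 1.09 CPM (edgeR adjusted p = 0.349).

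Decidual stromal genes changed singly. Igfbp3 rose 2.05-fold to 1388 ± 140 CPM and Prl3c1, a decidual prolactin family gene, rose 2.16-fold. Fkbp5, a progesterone-responsive immunophilin gene, fell 1.68-fold and Angpt4 fell 1.77-fold. Prl8a2, the decidual prolactin-related protein gene (chromosome 13, 27345673 to 27354216, plus strand), was at 11860 ± 2329 CPM in BPH/5 and 9303 ± 1412 in C57 and was not called (edgeR adjusted p = 0.069), though it was without BPH/5 2 (edgeR adjusted p = 0.012, range over all alternatives 0.012 to 0.91), with upper-quartile scaling (0.037) and in DESeq2 (0.041). With the length trend removed, its log2 fold change went from 0.35 to 0.04 (edgeR adjusted p = 0.835). Of 30 tested, 14 were higher, 8 lower and 8 not called (15 and 8 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.39). Ptgs2, the inducible cyclooxygenase gene (chromosome 1, 150100031 to 150108227, plus strand), was at 118 ± 8.98 against 73.5 ± 7.06 CPM, 1.61-fold higher (edgeR adjusted p = 4.75e-05). Hpgds, a prostaglandin D synthase gene, rose 1.94-fold, and Slco2a1, a prostaglandin transporter gene, fell 2.67-fold. Of 20 tested prostaglandin genes, 5 were higher, 4 lower and 11 not called, the same adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.54).

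Interferon-stimulated genes were lower in BPH/5, with 2 of 27 higher, 17 lower and 8 not called (2 and 18 adjusted over the list alone). Their median was -0.44 (camera adjusted p = 0.0038, and adjusted p = 0.83 with an estimated correlation). Rsad2, an antiviral effector gene, fell 2.84-fold, the guanylate-binding protein gene Gbp3 1.83-fold and the transcription factor gene Stat1 1.47-fold, while Irf7, another transcription factor gene of the pathway, rose 1.56-fold. MHC genes had 3 of 22 higher, 11 lower and 8 not called (4 and 11 adjusted over the list alone), with a median of -0.36, also with H2-L at its bound (camera adjusted p = 0.018, and adjusted p = 0.83 with an estimated correlation). H2-T23, which encodes a nonclassical class I molecule, fell 7.71-fold and H2-Q4 3.52-fold, H2-T10 rose 7.94-fold, and H2-L had no fragment in BPH/5, at least 36.2-fold lower. MHC genes vary between strains and resemble one another, so single members are uncertain, and H2-L had no matched transcript. Both groups were counted against the build mm10, and whether variants between the strains moved the list as a whole was not tested. In both lists the scores of C57 3 and 4 were highest (0.40 and 0.37 for interferon-stimulated genes, 0.32 and 0.32 for MHC genes).

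Immune cell markers changed in part. Of 27 uterine natural killer cell genes, 3 were higher, 11 lower and 13 not called, the same adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.11). The list was called without BPH/5 3, BPH/5 4 or C57 2 (camera adjusted p = 0.024, 0.043 and 0.048) and with the length trend removed (0.025), within a range over all alternatives of 0.024 to 0.83. The receptor genes Klrb1c and Cd244 (now Cd244a) fell 7.32-fold and 6.24-fold. Klra8, of a family that differs between strains, had 1 fragment in BPH/5 and 359 in C57 (a ratio of 349, interval 62.3 to 13800). Whether variants between the strains moved the counts of these receptor genes was not tested, so their falls do not show fewer natural killer cells. The granzyme gene Gzmk rose 15-fold to 3.25 ± 1.39 CPM. Macrophage and dendritic cell genes had 6 of 27 higher, 5 lower and 16 not called, the same adjusted over the list alone (median -0.09, mean 0.03, camera adjusted p = 0.91). Lyz2 rose 2.06-fold and Trem2 fell 4.67-fold. Neutrophil genes, a list that shares Ltf and Lcn2 with the epithelium, had 6 of 9 higher, 2 lower and 1 not called, the same adjusted over the list alone (median 0.91, camera adjusted p = 0.11, 0.043 without BPH/5 2, and 0.0028 to 0.83 over all alternatives). T and B lymphocyte genes had 4 of 11 higher, 2 lower and 5 not called (4 and 3 adjusted over the list alone, median 0.01, camera adjusted p = 0.87). After correction for the length trend, 3 were higher and 4 lower. Ctla4 rose 2.90-fold and Cd6 fell 3.31-fold. Cytokines and chemokines had 8 of 23 higher, 2 lower and 13 not called, the same adjusted over the list alone (median 0.25, camera adjusted p = 0.22), among them Csf1, the macrophage growth factor gene (2.82-fold higher), Ccl8 (5.01-fold), Il1a (2.85-fold) and Cxcl12 (1.82-fold). Correcting the length trend gave 8 higher and 5 lower. The list was called without C57 3 and 4 together (camera adjusted p = 0.032, range over all alternatives 0.032 to 0.83).

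The remaining lists held changes in both directions and were not called. Endothelial genes had 5 of 26 higher, 7 lower and 14 not called, the same adjusted over the list alone (median -0.11, camera adjusted p = 0.43). Cdh5 and Vwf fell 1.95-fold and 2.64-fold, and Sox18 rose 1.27-fold, a call lost with length and GC trends removed (edgeR adjusted p = 0.051, range over all alternatives 2.4e-05 to 0.051). Hypoxia and glycolysis genes had 12 of 28 higher, 4 lower and 12 not called, the same adjusted over the list alone (median 0.25, camera adjusted p = 0.11), with Car12 4.57-fold and Bnip3 1.5-fold higher and Epas1, which encodes HIF-2α, 2.11-fold lower at 824 ± 87.4 CPM. Renin-angiotensin and vasoactive genes had 9 of 21 higher, 7 lower and 5 not called, the same adjusted over the list alone. Their median was -0.03, their mean 0.02 and camera's direction up (camera adjusted p = 0.87), which turned under upper-quartile scaling (0.97, range over all alternatives 0.61 to 1). The natriuretic peptide gene Nppa rose 8.52-fold and Nos2 1.86-fold, and Gucy1b3, a subunit of the nitric oxide receptor (now Gucy1b1), fell 2.09-fold and Ece1 1.51-fold.

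Leptin and lipid handling genes had 7 of 24 higher, 9 lower and 8 not called, the same adjusted over the list alone (median -0.04, mean 0.05, camera direction down, adjusted p = 0.81). Fabp5 rose 1.86-fold, Retn rose 4.06-fold and Ldlr fell 1.69-fold. Progesterone and steroid metabolism genes had 4 of 14 higher, 5 lower and 5 not called (4 and 6 adjusted over the list alone, median -0.22, camera adjusted p = 0.63). Hsd11b2, which inactivates glucocorticoids, rose 2.00-fold, Cyp26a1, which degrades retinoic acid, rose 1.74-fold, and the coactivator gene Ncoa2 fell 1.65-fold. Oxidative stress genes had 11 of 26 higher, 6 lower and 9 not called, the same adjusted over the list alone (median -0.02, mean 0.01, camera direction up, adjusted p = 0.87). With the length trend removed the balance turned, to 6 higher and 10 lower (median -0.14, camera direction down, adjusted p = 0.47, range over all alternatives 0.47 to 0.98). Gpx1 rose 2.14-fold, while Nox4, an NADPH oxidase gene, fell 2.58-fold and Gsr 1.79-fold. Cell cycle genes had 8 of 27 higher, 2 lower and 17 not called (7 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.37), with Ccnb2 1.43-fold higher and Rrm2 1.36-fold lower. Immediate early and heat shock genes had 8 of 22 higher, 2 lower and 12 not called, the same adjusted over the list alone (median 0.14, camera adjusted p = 0.20), with Ier3 1.82-fold and Btg2 1.42-fold higher. Correcting the length trend gave 4 higher and 3 lower (median 0.07).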

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

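The tests of the length trend, of shared sequence and of conceptus markers were chosen after the results they bear on were seen, as were the fits with a trend removed, without C57 3 and 4 and on thinned libraries. Single libraries stood apart from the others of their group in 15 of 303 groups of 4 values, and chance alone gives about 15.2, 1 in 20. The number given for each is the library's gap to the nearest other divided by the range of the group.

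In BPH/5 1, Igfbp3 was at 1600 CPM against 1300 to 1350 in the others (0.836), Csf1 at 52.2 against 58.9 to 59.6 (0.906) and Eln at 115 against 167 to 178 (0.835). In the same library Prl3d2 was at 0.745 CPM against 0.0399 to 0.152 (0.84), without which its log2 fold change went from -3.90 to -5.12, and Trim12a was at 0 against 0.0358 to 0.0399 CPM (0.897), 1 fragment in each of the others. In BPH/5 2, Eng was at 97.9 CPM against 118 to 120 (0.907) and Fkbp5 at 250 against 291 to 295 (0.918). In BPH/5 3, Ncoa2 was at 38.1 CPM against 44.3 to 45.1 (0.878), and Klra8 was at 0.0399 against 0 in the others (1.0), a single fragment. In C57 1, Kdr was at 87.7 CPM against 111 to 115 (0.874), and the library's correlation of expression with transcript length was 0.01 against 0.32 to 0.38 (0.838). In C57 2, Clca1 was at 17.0 CPM against 13.9 to 14.2 (0.895), Alas2 at 2.42 against 4.44 to 4.83 (0.839) and the uterine epithelial score at -0.59 against -0.43 to -0.41 (0.889). In C57 3, the neutrophil score was -0.15 against -0.52 to -0.49 (0.919).

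A first pattern is that 49.2% of tested genes were called. With the length trend removed, 76.2% of the called genes kept call and sign, which argues against the trend as the whole cause. With every library thinned to the smallest total, 7139 genes were called against 7326. Totals were alike before thinning, from 21966594 to 27943295 fragments, so thinning could hardly change the count and does not decide on depth. Only 1 of the 35 splits of the 8 libraries, the real one, gave 7326 calls, and the highest of the others gave 0. The same held for the 1307 genes of at least 2-fold change (1 of 35, highest other 0). The real grouping thus stands apart, but every other split mixes the groups, which raises the spread within them. With 35 splits, and sites that may share a dam, a chance difference between the groups' sites is not excluded. What stays open is the strain itself and whatever else differed between the groups' sites, such as stage, the share of uterine tissues or processing day, which were not tested.

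A second pattern is the lower level of trophoblast genes. With the length trend removed their median log2 fold change was -1.49 (95% bootstrap interval over genes -2.34 to -0.71). Before, it was -1.24 (-2.3 to -0.57). The median did not weaken, which argues against that trend as the cause. Genes of the list move together (estimated correlation 0.38), so these intervals are too narrow and leave out the spread between libraries. Without C57 3 and 4, 6 of the 12 genes called lower were still called, and all 12 stayed lower in value. The median was then -0.41 against -1.24, so part of the size of the difference came with those libraries. For the lost calls, those libraries cannot be told apart from fewer samples. Less conceptus tissue in the BPH/5 sites may also account for it. The 1 gene that lies in more than 1 conceptus list was left out here. Medians were then -1.48 for trophoblast, -1.16 for epiblast and -0.34 (interval -1.6 to 0.32) for visceral endoderm genes. A permutation test over genes with 100000 permutations did not part the lists (p = 0.23). That decides neither way, because the last interval holds 0 and neither the interval nor the test counts the spread between libraries. A strain difference in trophoblast stays open and was not tested.

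Another pattern is that 67 called genes lay at least 16-fold apart, 38 higher and 29 lower. Of the 62 with a known transcript, 27 (43.5%) shared at least 10% of their 30-base words with another gene, against a median of 12.9% and a highest of 30.6% in 10000 sets matched on expression (one-sided permutation p = 1e-04, the smallest these sets can give), which is consistent with reads assigned differently among copies, and 35 had no such sequence. Among those with a position, genes whose symbols start with the same letters were counted as 1 per window of 5 megabases. The 58 genes left filled 46 windows, against a median of 53 in random draws (one-sided permutation p = 0.002), as linked segments that differ between the strains would give. Relatives with unlike symbols, or with Gm and Rik symbols, were not merged, so families of neighbouring genes cannot be told apart from such segments. Real differences in regulation or gene content between the strains stay open beside both, and strain variants against the reference were not tested.

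The number of called lists does not set the real grouping apart: 18 of the 35 splits called 7 or more lists, and the highest of the others called 16, so chance cannot be excluded for that number.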

How the results depend on the processing

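The fits with a trend removed, without C57 3 and 4 together and on thinned libraries were chosen after seeing the data. The counts of genes called higher (3680) and lower (3646) stayed within 1.5 times under the alternatives that kept all libraries, from 3127 to 4395 higher and from 3053 to 4085 lower, and were 2128 and 2090 without C57 3 and 4, where fewer samples were tested. Of the called genes tested under an alternative, 76% to 99.8% were called there with the same sign, and 55.6% without C57 3 and 4. At least 2-fold changes (689 higher, 618 lower) fell to 420 higher under the stricter filter, to 275 and 257 on log2(FPKM + 1), 393 and 387 on log2(FPKM + 0.1), and 295 and 270 on log2(FPKM + 1) without a filter; the stricter filter tests fewer genes, while between the filtered FPKM fits only the pseudocount differed, and the part of their fall that came with test, normalization or filter was not tested. Called lists (7) went to 0 when camera used each list's estimated correlation, 0.037 to 0.526 in those 7 lists, in place of 0.01, and to 15 with fry, which asks another question. Leaving out 1 library gave 2961 to 3854 higher, 3006 to 3761 lower, 678 to 754 and 576 to 699 of at least 2-fold, and 6 to 9 lists. Of 3380 values of 142 genes, 3328 kept sign and side of the threshold, 45 lost the call, 6 gained it and 1 turned, Prl8a2 at -0.03 with length and GC trends removed. Of 750 list values, 693 kept both, 15 lost, 21 gained and 21 turned. All that turned were uncalled in both fits, and the cause was not tested. Their adjusted p was 0.97 (upper quartile) and 0.98 (no filter) for vasoactive genes, 0.52 (stricter filter), 0.47 and 0.44 (FPKM, pseudocounts 1 and 0.1) and 0.81 (without C57 3 and 4) for visceral endoderm, and 0.92 with either trend correction, 0.8 without C57 3 and 4 and 0.73 by fry for angiogenic genes. It was 0.47 and 0.53 with the trend corrections for oxidative stress genes, and 0.65 without C57 3 and 4 and 0.95 on thinned libraries for macrophages. Over single left-out libraries it ran from 0.81 to 0.98 for vasoactive genes, 0.78 to 0.98 for oxidative stress, 0.72 to 0.99 for macrophages and 0.76 to 0.99 for lymphocytes, lists that turned in at least 1 of these. With the replicate number as a block, 3521 genes were higher and 3610 lower and 8 lists were called. The numbers do not pair the samples: pair correlations were -0.09, 0.20, -0.01 and 0.18, and 2 of 4 libraries in each group correlated best with their own number. Depth limits genes under about 0.14 CPM, the level of 3 fragments in the smallest library.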

Other observations

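The lists below, the genes named from them and the test of mast cells were chosen after the data had been seen. Genes listed for mast cells, not all of them particular to that cell type, had 6 of 8 tested higher in BPH/5, 1 lower and 1 not called. Their median log2 fold change was 1.91 (camera adjusted p = 0.0049 over 4 added lists, adjusted p = 0.45 with an estimated correlation). Tpsab1 is among them and had been seen to be higher when the list was chosen, so the camera result is no independent support. Beside Tpsab1, Cpa3 was at 2.00 ± 0.826 against 0.173 ± 0.0458 CPM (11.3-fold, n = 4), Mcpt8 was 5.68-fold, Tpsb2 2.49-fold and Hdc, the histidine decarboxylase gene, 2.32-fold higher. Kit, a receptor of mast cells among other cell types, was at 59.8 ± 12.6 against 249 ± 30 CPM, 4.16-fold lower, and Gata2 was at 150 ± 5.43 and 143 ± 5.13 CPM (edgeR adjusted p = 0.373). Ribosomal protein genes had 71 of 81 higher and 1 lower (median 0.43, camera adjusted p = 3e-13, adjusted p = 0.45 with an estimated correlation), and with the length trend removed 45 higher and 4 lower (median 0.18, camera adjusted p = 1.3e-05). Respiratory chain genes had 61 of 86 higher and 2 lower (median 0.32, camera adjusted p = 2.7e-08, adjusted p = 0.45 with an estimated correlation), and with the length trend removed 27 higher and 13 lower (median 0.05, camera adjusted p = 0.24). The median transcript lengths of these lists were 1094 and 1215.5 nucleotides. Imprinted genes had 2 of 19 higher and 6 lower (median -0.15, camera adjusted p = 0.17), with Peg10 5.32-fold, Phlda2 3.95-fold and H19 2.04-fold lower and Sgce 1.85-fold higher. Peg10, Phlda2 and H19 were uneven in C57, as trophoblast genes were, but Peg10 and Phlda2 are themselves on the trophoblast list. Peg10 was at 14.3, 6.03, 32.2 and 33.4 CPM in C57 1 to 4 against 4.06 ± 0.443 in BPH/5. Phlda2 was at 2.68, 1.23, 4.67 and 4.26 against 0.812 ± 0.130, and H19 at 101, 49.2, 138 and 144 against 53.0 ± 8.32. Dlk1, also called lower, was even in C57, at 3.655 ± 0.198 CPM against 2.71 ± 0.446 in BPH/5.

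A hypothesis is that BPH/5 sites held more mast cells, which should raise mast cell genes of other families than the chymases and tryptases as well. The test covered only the 4 tested genes outside these families, and their median was 0.64 with a 95% bootstrap interval of -2.06 to 3.5. With so few genes that interval is their full range, from Kit to Cpa3, so the test could not decide. Kit (59.8 CPM in BPH/5 and 249 in C57) and Gata2 (150 and 143) also lay far above Cpa3 (2.00 and 0.173). They may thus follow other cell types of the site, and more genes of that kind would not decide it either.

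Y-linked genes had 18, 6, 7 and 12 fragments in BPH/5 1 to 4 and 2, 0, 89 and 85 in C57 1 to 4, where a count of 0 allows up to 3. None of these genes was tested for a difference between the strains, and no library was grouped by them.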
